A study of Mus musculus with 24 samples.

How the data were processed

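RNA samples of mouse CD4 T cell clones were hybridised to Affymetrix arrays, 4 arrays for each of 6 clones and 24 in all. Per the labels' protocols, the clones were restimulated weekly with antigen on antigen-presenting cells, rested in medium with 3 ng/ml IL-7 for 48 h before extraction, and labelled with biotin from 100 ng of total RNA by the WT Plus procedure. Per the submitters' processing notes, the deposited values were made with RMA, which corrects background, applies quantile normalization and summarises probes into probe sets, in Partek 6.6. The log2 values deposited by the authors, 1 per probe set and array, were used as deposited. The log base was not given in the sources used here and was read as 2 because the values run from 2.76 to 14.49. If the base were another one, the folds below and the genes that reach the fold minimum would change.

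The table holds 22206 probe sets, of which 19572 carry 1 gene symbol in the table of the array's probe genes, 0 carry several and 2634 are unnamed here. For the 55 genes with over 1 probe set the one with the highest mean was kept, which left 19505 genes. T cell receptor segments and Gata3 are among the genes not analysed here. The array gives a signal over background for each probe set and no read depth, so the number of arrays limits the precision. Array medians ran from 6.73 to 6.98 on the log2 scale.

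Groups, comparisons, gene lists and alternatives were fixed before the data were examined, except the alternative without 6 arrays that stand apart from their clones (a spread of deviations from the clone mean over 1.25 times that of the median array). The phenotype of each clone comes from its phenotype label; the sample titles of clone 16-18 carry the same prefix as those of clone 12-17, although its phenotype label gives both cytokines. The growth protocol ties clone 3-10 to splenocytes and clones 12-7, 13-11 and 13-7 to B cells as antigen-presenting cells, and it does not clearly name clones 12-17 and 16-18. Whether the 4 arrays of a clone came from separate cultures is not stated, so p-values measure the spread between arrays. No hybridisation date or slide is given. The 24 arrays hold 0 pairs with identical values.

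A linear model with 1 mean per clone was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 18 residual degrees of freedom), with Benjamini-Hochberg adjustment over genes within a contrast and a threshold of 0.05. Genes differing among the clones were taken from the moderated F test. Comparisons between clones required the same direction, an adjusted p under 0.05 and at least a 2-fold difference in every clone pair involved. For the phenotype comparison the clone is the replicate, so a second limma fit used 1 mean per clone, 2 clones against 3. The 30 genes of the pairwise rule were set beside the 9 other ways of choosing 2 of the 5 clones. Gene lists, 28 of them with 452 of 504 symbols measured here, were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over lists within a comparison. The list tests used the clone-level fit for the phenotypes and the 24-array fit for the other comparisons.

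Named genes were chosen by a rule: up to 12 genes highest and 12 lowest in the phenotype comparison, and 8 and 8 for clones 12-17 and 3-10, by the smallest difference over the clone pairs, without receptor segments and predicted symbols. List members that passed every pair may be named, and Ifng, Il13, Il4, Il5 and Tbx21 are given whatever their values. Genes named for setting a single clone apart from all others, and Cd4, Cd3e, Cd8a, Cd8b1 and Cd79a, were chosen outside this rule, after their values were seen.

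The functions were tested on simulated arrays built from the real gene means and spreads with 200 changed genes. In runs with no other difference between clones and a log2 change of 2, the pairwise rule recovered 100% of the changed genes for the phenotype comparison. It recovered 98% for clone 12-17 and 96% for clone 3-10, with 0 false calls over 19505 genes in each. Differences between clones of the size seen here were then added, for the phenotype comparison only. The clone-level fit recovered 80% at a log2 change of 2 with 12 false calls, and the pairwise rule recovered 92% with 35 false calls. The changed genes were drawn at random from all genes, of which 31.9% differed among the real clones in the moderated F test. These recoveries may therefore not hold for genes that vary widely among clones. In the real clone-level limma fit Eomes, with a mean log2 difference of 4.47, had an adjusted p of 0.976. Alternatives covered the replicate number as a block, other normalizations and filters, other thresholds, leaving out each array or clone, and moving clones 12-17 and 3-10 between groups. Neighbouring genes were found by ordering genes by chromosome and start position in the RefSeq gene table of GRCm38.p6. No coordinates are printed here. Figures were drawn with matplotlib 3.10.9.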

Results

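The series profiled 6 mouse CD4 T cell clones raised against Chlamydia antigen from immune mice, each on 4 arrays. By their labels, clones 12-7, 13-11 and 3-10 make interferon gamma (IFN-g clones), clones 13-7 and 16-18 make interferon gamma and IL-13 (IL-13 clones), and clone 12-17 is labelled as having lost IL-13. Cd4 lay between 12.90 ± 0.14 in clone 13-7 and 13.35 ± 0.07 in clone 3-10 (log2, mean ± SD, n = 4), and Cd3e, a chain of the CD3 complex, between 13.36 ± 0.08 and 13.51 ± 0.07. Arrays of the same clone correlated with a median of 0.990 over genes, against 0.971 for arrays of different clones. Genes are not independent replicates in these correlations.

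The first question was how far the clones differ at all. Each clone had genes that set it at least 2-fold above all 5 others. Clone 12-17 led with Sgce (10.12 ± 0.17, the next clone at 5.36) and Foxf2, a forkhead transcription factor, at 8.84 ± 0.13 against 4.67. Clone 13-7 alone had the mast cell protease Cpa3 at 10.10 ± 0.58 (next clone 5.87) and Cd93 at 9.44 ± 0.22 (next 5.54). Clone 16-18 alone had Lrrc32, which encodes the TGF-beta anchoring protein GARP, at 9.47 ± 0.66 (next 5.58), and the steroid-synthesis enzyme Cyp11a1 at 7.76 ± 1.07 (next 4.36). Clone 3-10 alone had the enamel gene Amelx at 12.04 ± 0.35 (next 6.14) and Ebf1, a transcription factor of B cell development, at 10.94 ± 0.13 (next 5.76). In clone 12-7 the X-linked gene Xlr3b led, at 8.09 ± 0.22 (next clone 4.27). Slc27a6 at 10.19 ± 0.21 (next 7.33) and the X-linked Xlr3c at 7.09 ± 0.13 (next 4.29) followed. In clone 13-11 the scavenger receptor Cd36 lay at 8.51 ± 0.79 (next 5.59). All of these differences passed the limma fit, the largest adjusted p being 0.000124 for Cd36. Clones 13-11 and 3-10 had the most such genes, 106 higher and 106 lower in clone 13-11 and 100 higher and 135 lower in clone 3-10. Clone 13-7 had the fewest, 31 higher and 3 lower. Across the 6 clones 6221 of 19505 genes (31.9%) differed in the moderated F test. Pairs of clones differed by 459 genes (13-7 and 16-18) to 1196 genes (12-17 and 13-11) at 2-fold, with a median of 969. Clone 12-17 was nearest to clone 12-7, with 490 genes.

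The design text asks for differences between the T cell subsets, here the IL-13 clones against the IFN-g clones. In all 6 pairs of an IL-13 clone with an IFN-g clone, 25 genes were higher and 5 lower in the IL-13 clones. Cd6, a surface receptor that tunes T cell receptor signalling, was 7.41-fold to 53.0-fold higher in the 6 pairs, with clone means of 11.79 ± 0.15 and 10.56 ± 0.33 against 6.06 ± 0.31 to 7.67 ± 0.51 (n = 4 each, largest adjusted p over the pairs 8.44e-09). Cd5, its relative, was 5.41-fold to 37.1-fold higher (largest adjusted p 1.37e-09), and Trat1, an adaptor of the receptor complex, was 5.32-fold to 16.6-fold higher (0.000935), with a smallest fold of 8.94 without replicate 4 of clone 13-7. The T-box factor Eomes lay at 10.51 ± 0.46 and 11.87 ± 0.07 in the IL-13 clones and at 5.61 ± 0.10 to 8.26 ± 0.24 in the IFN-g clones (largest adjusted p 1.35e-06).

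**Figure D1:**
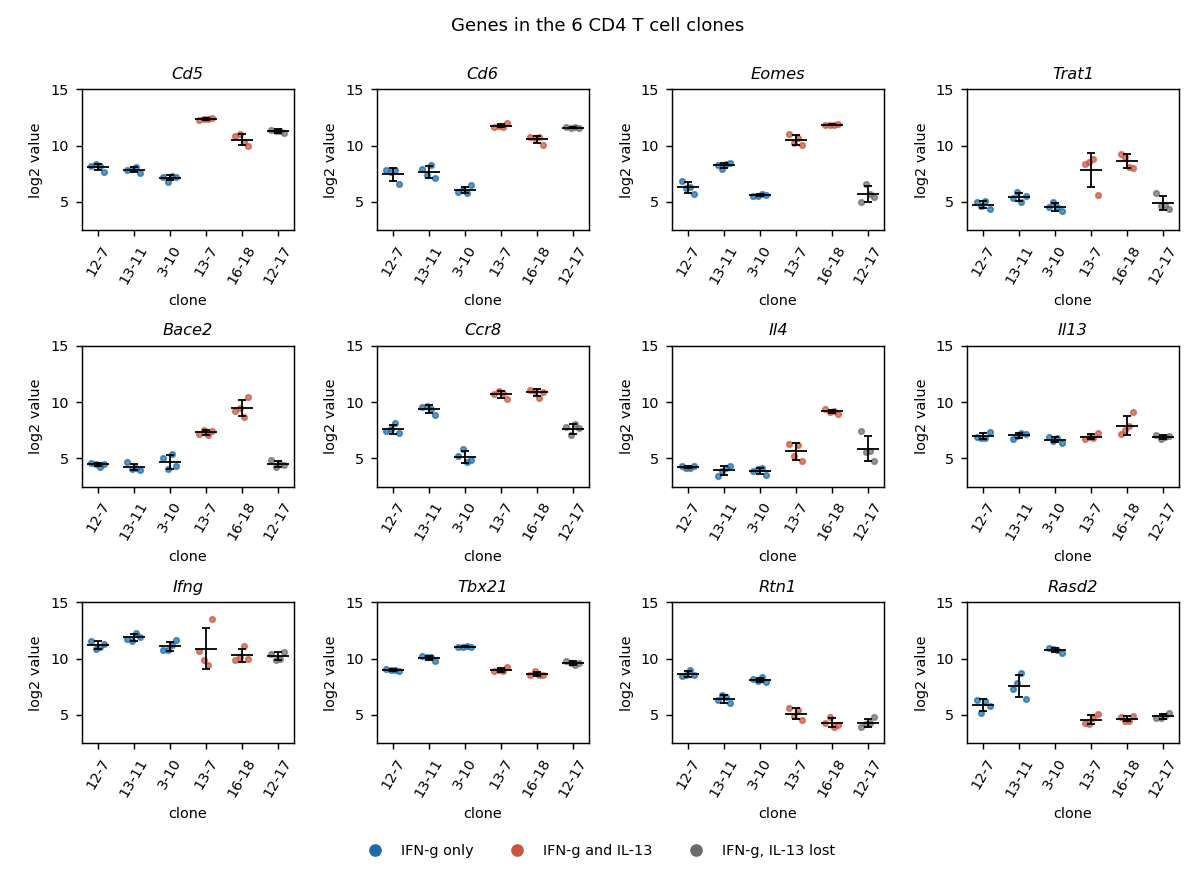
Log2 values of 12 genes (y axis) in the 6 clones (x axis), with 1 point per array, horizontal marks for the clone mean and bars for the SD (n = 4), coloured by labelled phenotype. Cd5 and Cd6 in clone 12-17 lie with the IL-13 clones, Eomes and Ccr8 with the IFN-g clones, and Il13 stays between 6.67 and 7.05 in 5 clones against 7.92 in clone 16-18.

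Of the 21 measured members of the Th2 list, 2 were higher in every pair, over all genes and adjusted over the list alone, and 19 did not pass. These were Il4, the signature Th2 cytokine, at 5.64 ± 0.75 in clone 13-7 and 9.19 ± 0.16 in clone 16-18 against 3.88 ± 0.28 to 4.26 ± 0.09 (largest adjusted p 0.0296, with a mean log2 difference of 3.38), and the chemokine receptor Ccr8, 2.47-fold to 52.3-fold higher. Il4 did not pass when any 1 array of clone 12-7, or replicate 1 or 3 of clone 13-7, was left out, with differences of 3.27 to 3.39. Il13 itself did not pass (mean log2 difference 0.52). It was 7.92 ± 0.85 in clone 16-18 and 6.93 ± 0.24 in clone 13-7, the latter within the 6.67 to 7.05 of the IFN-g clones. The cytokine values here are RNA of cells rested for 48 h in IL-7. Cytokine release and RNA shortly after antigen were not measured, so these values do not test the cytokine labels. Il5 lay between 5.06 and 5.67 in these 5 clones and did not pass. Ifng was high in all, at 10.87 ± 1.83 in clone 13-7 and 10.30 ± 0.57 in clone 16-18 against 11.12 ± 0.40 to 11.90 ± 0.31 in the IFN-g clones. Its mean log2 difference of -0.82 was negative in all 6 pairs and passed in 0 (smallest pair adjusted p 0.0517 in limma, clone-level unadjusted p 0.0468 and adjusted p 0.976), and it was -1.26 without replicate 4 of clone 13-7. Tbx21, the Th1 factor T-bet, did not pass either, at 8.65 ± 0.20 and 9.03 ± 0.18 in the IL-13 clones and 8.96 ± 0.08 to 11.07 ± 0.02 in the IFN-g clones. Other genes higher in every pair were the protease Bace2 (mean log2 difference 3.92), Rgs10 (2.84), Gpx8 (2.82), Hsd17b11 (2.78), the activin receptor Acvr2a (2.68), Carmil1 (2.08) and Oit3 (at least 2.94-fold in each pair). The 5 lower genes were Rasd2 (-3.47), Rtn1 (-3.04), Fbxo27 (-2.71), Edaradd (-1.63) and Podnl1 (-1.62). Rasd2 did not pass without replicate 1 of clone 12-7 (-3.42) or replicate 2 of clone 13-7 (-3.40), nor Podnl1 without replicate 2 or 3 of clone 12-7, 1 or 2 of clone 13-7, or 1 or 2 of clone 13-11 (-1.61 to -1.54). Without replicate 4 of clone 13-7 there were 9 lower genes, and without the 6 arrays that stand apart from their clones there were 12. With clone 3-10 left out, 39 genes were lower.

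With the clone as the replicate (2 against 3), limma called 0 genes at adjusted p under 0.05. The smallest adjusted p was 0.587, and 604 genes (3.10%) had an unadjusted p under 0.05, 301 higher and 303 lower, where no difference would give about 5%. The other 9 ways of setting 2 of these 5 clones against 3 gave 12 to 116 genes by the same pairwise rule, with a median of 30. The choice by phenotype thus gave as many genes as the median of the others.

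**Figure D2:**
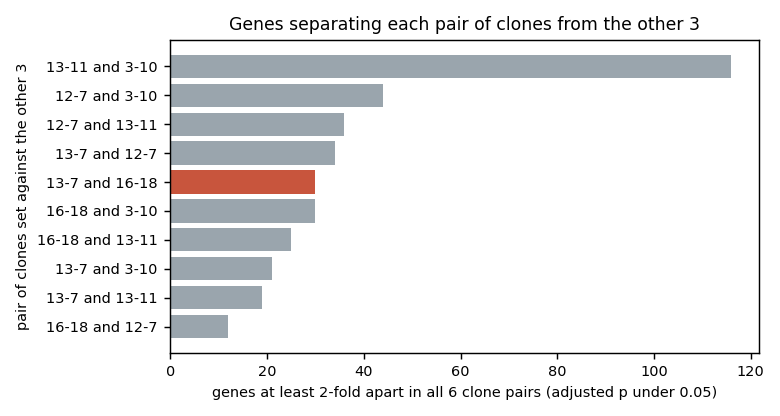
Number of genes (x axis) at least 2-fold apart in all 6 clone pairs for each choice of 2 of the 5 clones (y axis), with the labelled IL-13 clones in red. The choice by phenotype gave 30 genes and the others 12 to 116.

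As groups, 7 of 28 lists passed camera with its preset correlation. The cell cycle list was higher in the IL-13 clones, with a median difference of 1.04 over 30 members (adjusted p = 1.26e-11, which became an adjusted p of 0.579 with an estimated correlation) and 0 members passing every pair. Its clone medians ran from 8.67 in clone 13-11 and 9.42 in clone 3-10 to 10.65 in clone 12-7, beside 10.79 and 10.38 in the IL-13 clones. The Th2 list (median 0.37), the inhibitory receptors (0.31, with Cd5 passing) and the interferon-stimulated genes (0.56) were also higher, but did not hold with an estimated correlation (adjusted p = 0.579 for each). The myeloid markers (-0.65), the Th1 list (-0.34, in which Eomes passed in the opposite direction) and the Th17 list (-0.13) were lower and did not hold either (adjusted p = 0.579 for each), and the mean differences of the Th1 and Th17 lists turned to 0.050 and 0.044 without clone 16-18. Leaving out a single clone also ended the calls of the interferon-stimulated list (12-7 or 3-10), the inhibitory receptors (13-11 or 3-10), the myeloid markers (13-11) and the Th17 list (12-7), the last also ended without the genes of lowest expression. The interferon-stimulated list turned to a mean difference of -0.11 without the 6 arrays that stand apart. In 1 array each of clones 13-7, 13-11 and 16-18 all 26 of its measured members lay above their clone mean, by 1.96 to 2.93 on average, and Ifng in the one of clone 13-7 was 13.50 against 9.43 to 10.69 in the clone's other arrays. Median, mean and test differed in sign for 6 lists that did not pass, those of chemokine receptors, chemokines, follicular helper cells, integrins, glycolysis and CD8 or gamma-delta T cells.

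Clone 12-17 lets the label of lost IL-13 be set against the IL-13 clones, although with 1 clone the label and the clone cannot be told apart. Il13 was 6.93 ± 0.18 in clone 12-17, the value of clone 13-7, and 0.99 below clone 16-18. Il4 stood at 5.88 ± 1.13, and neither passed, nor did Ifng (mean log2 difference -0.36, and 0.08 without replicate 4 of clone 13-7), Il5 (-0.42) or Tbx21 (0.78). As RNA of rested cells, these values do not test the label of lost IL-13. The largest gains over both IL-13 clones were the enamel gene Ambn (44.7-fold in the nearer pair, also 12.95 ± 0.13 in clone 12-7), Sgce (40.4-fold), and S1pr1, the receptor that lets T cells leave tissue (11.40 ± 0.15 against 6.49 ± 0.79 and 5.93 ± 0.69). Csn2, Foxf2, Srgap1, Eps8l1 and Gja1 followed at 28.6-fold to 16.6-fold. The largest losses were Cd226, a costimulatory receptor (5.34 ± 0.40 against 11.30 ± 0.08 and 11.79 ± 0.20), Plxdc2, the antiviral Ifitm3, Ms4a4b, Lipo3, Eomes (5.70 ± 0.70), Anxa2 and Gzmg. In all, 259 genes were higher and 221 lower than in both IL-13 clones (largest adjusted p among the named top genes 4.06e-05, for Gzmg). When clones 13-7 and 16-18 were each set against the remaining pair of this trio, 161 and 235 genes passed.

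The cytotoxic effector list was lower in clone 12-17, with a median difference of -0.31 and a mean difference of -1.02. Its clone medians were 9.49 in clone 12-17, 9.91 in clone 16-18 and 11.24 in clone 13-7, so the IL-13 clones themselves lay apart. Of 21 measured members 6 were lower, over all genes and adjusted over the list alone. The granzymes Gzmg (mean log2 difference -5.65), Gzmc (-4.74), Gzmf (-4.54) and Gzmb (-1.78), perforin (Prf1, -2.07) and the death ligand Tnfsf10 (-2.12) were lower, and the serpin Serpinb6b was higher (1.85). The list passed camera (adjusted p = 2.38e-06) and held with an estimated correlation (adjusted p = 0.00959). Gzmb (-1.47) and Prf1 (-1.91) did not pass without the 6 arrays that stand apart, nor Prf1 without replicate 4 of clone 13-7 (-1.81), nor Serpinb6b without replicate 2 or 3 of that clone (1.83 and 1.72). Of 29 tissue residency genes 5 were lower and 0 higher (1 higher adjusted over the list alone), among them the adhesion receptors Cdh1 (-4.45) and Itgae (-1.83) and the signalling regulator Rgs2 (-3.39). Itgae did not pass without those 6 arrays, nor without replicate 3 or 4 of clone 12-17 or of clone 13-7 (-1.82 to -1.67). Isg20 (-1.14) was a further one and did not pass when any 1 of most arrays was left out (-1.23 to -0.90). The list's adjusted p of 0.0229 became 0.456 with an estimated correlation. Of 18 recirculation genes 2, S1pr1 among them, were higher and 3 lower, and that list did not pass camera (adjusted p = 0.266). Of these 3, Slfn5 did not pass without replicate 1, 2 or 4 of clone 12-17 or replicate 4 of clone 13-7 (-4.02 to -3.67). Alongside, the integrin chain Itga4 was higher by 3.19 and Alcam lower by 3.04. In the Th2 list 3 members were higher and 3 lower, with Maf (3.26) and Ptgdr2 (1.87) above and Epas1 (-3.82) and Ccr8 (-3.15) below the IL-13 clones, Il31 (1.32) not passing without replicate 1 of clone 12-17 (0.98), and the list did not pass (adjusted p = 0.266). Slamf6, of the follicular helper list, was higher by 3.46.

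Interferon-stimulated genes had a median difference of -1.26 in clone 12-17, with 3 of 26 lower, Ddx58 (-4.02), Igtp (-1.33) and Gbp2 (-1.26), and an adjusted p of 1.36e-05 that became 0.546 with an estimated correlation. The IL-13 clones include 2 of the 3 arrays in which this whole list was high, and Igtp (-1.08) and Gbp2 (-0.75) did not pass without the 6 arrays that stand apart, nor Gbp2 without replicate 3 of clone 16-18 (-1.01). Of 22 myeloid markers 4 were higher in clone 12-17 (7 adjusted over the list alone), including the phagocyte oxidase chain Cybb (2.08), and 1, Ms4a6c (-1.52), was lower. Without replicate 4 of clone 12-17 only Cybb of the 4 passed, and Lyz2 (3.30), Mpeg1 (1.58) and Cd14 (0.89) did not. Lyz2 did not pass when any 1 array of clone 12-17, or replicate 3 of clone 16-18, was left out (2.93 to 3.54), nor Mpeg1 without replicate 2 or 4 of clone 16-18 (1.58 and 1.68), nor Cd14 without replicate 1 of clone 12-17, 4 of clone 13-7 or 2 or 3 of clone 16-18 (0.95 to 1.02), nor Cd14 (0.91) and Ms4a6c (-1.39) without the 6 arrays. H2-Aa of the class II list was higher (1.83). The adjusted p values of these lists, 0.00194 and 1.36e-05, became 0.396 and 0.25 with an estimated correlation. Glycolysis and hypoxia genes (median 0.59, 0 of 20 passing) were higher by camera (adjusted p = 8.66e-06, or 0.396 with an estimated correlation), and 5 further lists passed only at the preset correlation, with adjusted p = 0.187 (cytokine receptors, lower), 0.25 (follicular helper, higher), 0.253 (Th17, higher, with a median of -0.01 against a mean of 0.33), 0.546 (cholesterol synthesis, lower) and 0.689 (cell cycle, lower) with an estimated one. Median, mean and test also differed in sign for the lists of T cell identity, Th1, regulatory, NK, costimulatory, chemokine receptor and integrin genes, none of which passed. Without the 6 arrays that stand apart the tissue residency, Th17, cholesterol synthesis and cell cycle lists did not pass, nor did the Th17 list with median centring.

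**Figure D3:**
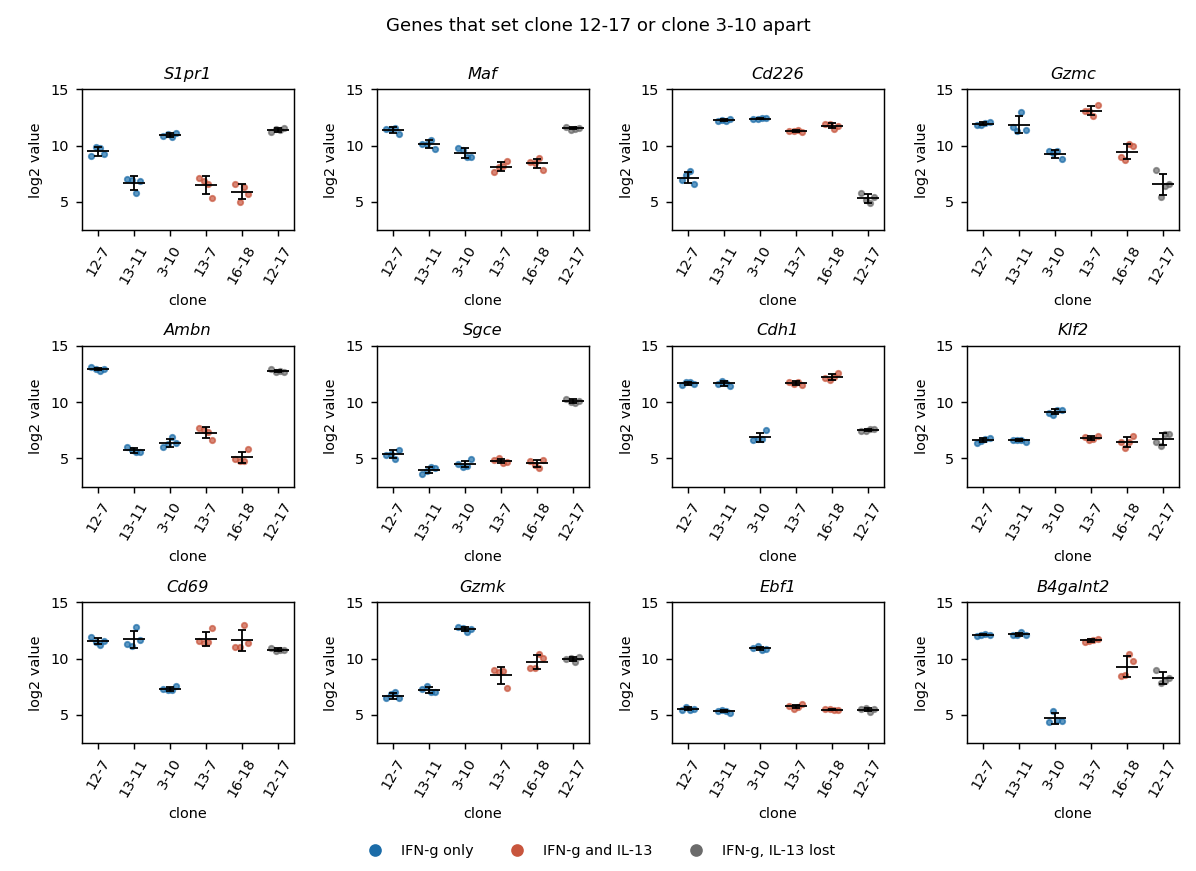
Log2 values of 12 genes (y axis) in the 6 clones (x axis), with 1 point per array, horizontal marks for the clone mean and bars for the SD (n = 4). Clone 12-17 is highest for Sgce and S1pr1 and lowest for Cd226, and clone 3-10 is highest for Klf2, Gzmk and Ebf1 and lowest for Cd69 and B4galnt2.

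On the 30 genes that separated the phenotypes in every pair, clone 12-17 lay nearer the IL-13 clones for 8 and nearer the IFN-g clones for 22. The 26.7% nearer the pair lay within the 5.17% to 70.5% that the other choices of 2 clones gave, and 6 of the 10 choices reached it. Cd5 (11.30 ± 0.14) and Cd6 (11.60 ± 0.03) were at the level of the IL-13 clones, as were the low values of Rtn1 and Rasd2. Eomes, Trat1, Bace2 and Ccr8 were at the level of the IFN-g clones. With clone 12-17 counted among the IL-13 clones, the pairwise rule gave 5 higher genes and 1 lower gene, and with it among the IFN-g clones 17 higher and 3 lower.

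Clone 3-10 was the clone kept on splenocytes, and its comparison with the other IFN-g clones, both kept on B cells, bears on the change of antigen-presenting cell named in the design text. With 1 clone on splenocytes, clone and antigen-presenting cell cannot be told apart. The genes highest in clone 3-10 were Plac8 (79.6-fold in the nearer pair), Amelx (59.7-fold), Car5b (54.9-fold), granzyme K (Gzmk, 43.5-fold, 12.66 ± 0.19 against 6.72 ± 0.26 and 7.21 ± 0.26), Ebf1 (42.0-fold), the effector and memory marker Ly6c2 (38.9-fold), Prl2c5 (33.2-fold) and Ly6c1 (31.8-fold). Without replicate 3 of clone 13-11, 1 of the interferon-high arrays, the folds of Ly6c2 and Ly6c1 in the nearer pair were 75.8 and 57.9. The lowest were the glycosyltransferase B4galnt2 (4.70 ± 0.46 against 12.12 ± 0.04 and 12.18 ± 0.13), St8sia1, Tjp1, Cdh1, Icosl, Cd69, Abca3 and Ccn3. Altogether 197 genes were higher and 332 lower than in both other IFN-g clones, while 472 and 423 genes set clones 12-7 and 13-11 apart from the remaining pair. The named top genes had adjusted p values of 4.28e-06 (Ly6c2) or smaller in the limma fit. Ifng (mean log2 difference -0.44), Il13 (-0.34), Il4 (-0.22) and Il5 (-0.09) did not pass. Tbx21 (1.55) was 1.98-fold higher in the nearer pair and so did not pass, but did without replicate 1 or 3 of clone 13-11 (1.56 in both).

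Of 29 measured tissue residency genes 9 were lower in clone 3-10, 1, P2rx7 (1.84), was higher and 19 did not pass, the same counts as adjusted over the list alone. P2rx7 did not pass without replicate 1 or 2 of clone 3-10 (1.45 and 1.67). Of the 9, Hic1 did not pass without replicate 4 of clone 3-10 (-1.35), and Rgs1 (-1.10) did not when any 1 of many arrays was left out, such as replicate 2 of clone 13-11 (-1.13). Cd69, which holds T cells in tissue, was 7.34 ± 0.17 against 11.58 ± 0.31 and 11.74 ± 0.76, Cdh1 was lower by a log2 difference of -4.80, Litaf by -2.88 and Itgae by -1.35. The recirculation factor Klf2 was 9.15 ± 0.22 against 6.64 ± 0.21 and 6.62 ± 0.10, and its target S1pr1 10.96 ± 0.14 against 9.49 ± 0.39 and 6.67 ± 0.60; of 18 recirculation genes these 2 were higher, 1 was lower and 15 did not pass. The camera calls (adjusted p = 6.77e-05 and 0.00871) became 0.0913 and 0.197, adjusted p with an estimated correlation.

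Of the regulatory T cell list 3 of 14 measured members were lower, Nt5e (-3.58), Ikzf2 (-1.63) and Ebi3 (-1.58), and the list held with an estimated correlation (adjusted p = 0.00792). Its clone medians were 8.90 in clone 3-10, 9.33 in clone 13-11 and 10.685 in clone 12-7. Foxp3 is not analysed here, and Ebi3 (-1.48) did not pass without the 6 arrays that stand apart. The chemokine list also held (adjusted p = 0.0246 with an estimated correlation), with 4 of 18 lower, Ccl9 (-3.34), Ccl6 (-3.03), Cxcl9 (-1.81) and Cxcl16 (-1.70). Within the cytotoxic list Gzmk was higher while 4 members were lower, among them Gzmb (-3.18), Gzma (-2.15) and Prf1 (-2.49), and the list did not pass (adjusted p = 0.0713). The NK receptor Klre1 was higher by 4.47 and Pparg, a lipid-sensing nuclear receptor of the Th2 list, lower by a log2 difference of -4.00. Of 22 myeloid markers 6 were lower (7 adjusted over the list alone), including Spi1 (-3.73), the myeloid transcription factor PU.1, and Cybb (-3.51), and 1, Ms4a6c (1.24), was higher, with an adjusted p of 2.57e-08 that became 0.0633 with an estimated correlation. Without replicate 4 of clone 3-10 only 3 of the 6 passed, and C1qb (-2.18), Itgax (-1.82) and Lyz2 (-3.43) did not, nor did Itgax without replicate 1 of clone 12-7 (-1.91) or Ms4a6c without replicate 2 of clone 3-10 (1.06). Ccl6, Ccl9 and Cxcl16 were highest in clone 13-11, as were Spi1 and Cybb. The MHC class II, Th2, inhibitory receptor, chemokine receptor, costimulatory, cytokine, follicular helper and interferon-stimulated lists were also lower and the glycolysis and NK receptor lists higher at the preset correlation. With an estimated correlation their adjusted p values were 0.156 (class II), 0.0633 (Th2), 0.0764 (inhibitory and chemokine receptors), 0.241 (costimulatory), 0.197 (cytokines and follicular helper), 0.618 (interferon-stimulated), 0.255 (glycolysis) and 0.244 (NK receptors). Median, mean and test differed in sign for the Th1, B cell, plasma cell and erythroid lists, which did not pass. The follicular helper list did not pass without the 6 arrays that stand apart, the NK receptor list with median centring, or the costimulatory list without the genes of lowest expression. In total 15 lists passed at the preset correlation and 2 with an estimated one.

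Transcripts of other cell types differed between clones. The macrophage lysozyme Lyz2 was 12.36 ± 1.01 in clone 13-11, 11.72 ± 0.33 in clone 12-17 and 10.83 ± 0.28 in clone 12-7, and 7.62 ± 1.54 to 8.82 ± 2.08 in the other 3 clones. Spi1 and Cybb had the same 3 clones highest. The B cell gene Cd79a stayed between 5.05 and 5.37 in all clones. Cd8a was 11.11 ± 0.15 in clone 16-18 and 8.94 ± 0.41 in clone 12-7, against 5.94 to 6.10 in the other 4, while Cd8b1 lay between 5.43 and 6.50 in all 6.

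**Figure D4:**
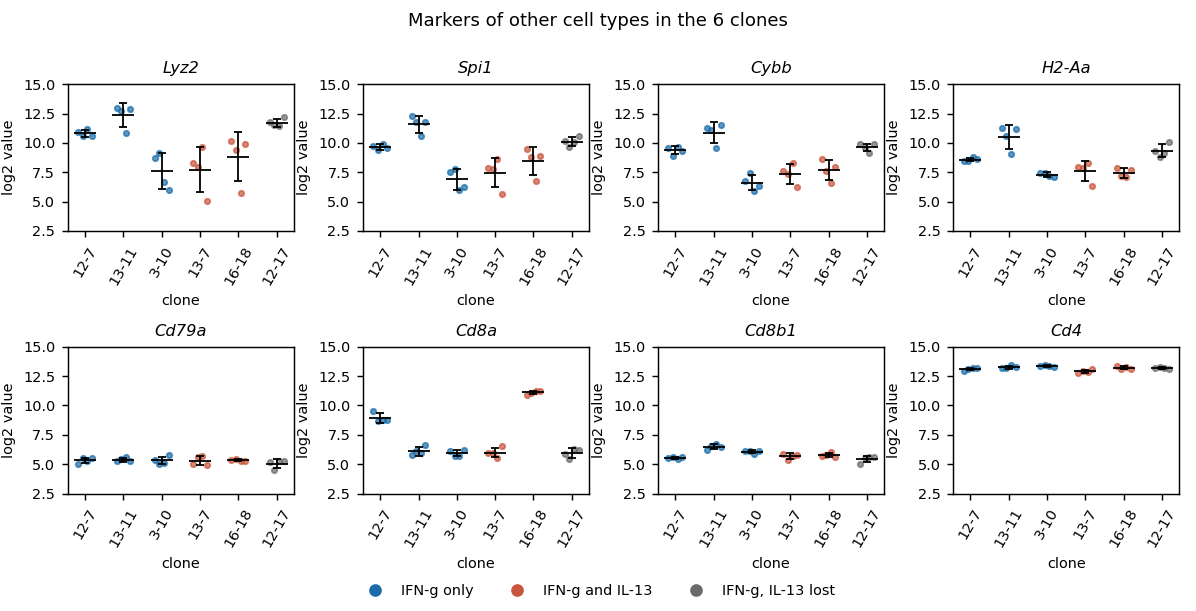
Log2 values of 8 genes (y axis) in the 6 clones (x axis), with 1 point per array, horizontal marks for the clone mean and bars for the SD (n = 4). Lyz2, Spi1 and Cybb are highest in clone 13-11, Cd79a is low in all 6 clones, and Cd8a is raised in clones 16-18 and 12-7 without Cd8b1.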

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

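Values of 100 named genes were examined in the 6 clones, 600 groups of 4 arrays. In 37 groups the highest or lowest array lay far from the other 3, where chance gives about 1 in 20 groups, and 22 of the 37 were in the 6 arrays that stand apart from their clones over all genes. The test of the myeloid genes in the 3 interferon-high arrays was chosen after the result was seen, as were the B cell and Cd8b1 tests and the values without the 6 arrays.

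In clone 13-11, replicate 3 was highest for Ddx58 (11.76), Igtp (12.86), Tnfsf10 (12.29), Ly6c1 (11.58), Gzmg (10.36) and Eps8l1 (4.86) and lowest for Lyz2 (10.86), Ccl6 (8.92) and S1pr1 (5.78). Replicate 1 was lowest for Prl2c5 (3.51) and replicate 4 for Klf2 (6.47). In clone 13-7, replicate 4 was highest for Cd69 (12.73) and lowest for Plxdc2 (12.09), Gzmk (7.43), Trat1 (5.61) and Gja1 (5.14), and replicate 1 was highest for Cyp11a1 (4.50). In clone 16-18, replicate 3 was highest for Ddx58 (11.70), replicate 2 for Tbx21 (8.95), Amelx (6.42) and Gja1 (5.23), and replicate 4 for Klre1 (7.92) and Ambn (5.85). In clone 3-10, replicate 4 was highest for Cdh1 (7.49) and Il5 (5.34) and lowest for Eps8l1 (3.46), and replicate 3 was lowest for Rgs2 (8.94). In clone 12-17, replicate 1 was highest for Ccn3 (12.76) and Igtp (10.79) and lowest for Oit3 (5.85) and Cd8b1 (5.04), replicate 2 was lowest for Rgs2 (6.69) and replicate 3 highest for Acvr2a (6.27). In clone 12-7, replicate 1 was highest for Cd8a (9.54), replicate 3 for Eps8l1 (8.39) and Hsd17b11 (8.25), and replicate 4 was lowest for Maf (11.05).

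Replicate 4 of clone 13-7, replicate 3 of clone 13-11 and replicate 3 of clone 16-18 shared a raised interferon-stimulated list, 1.96 to 2.93 above their clone means, while the other arrays of these clones lay at -1.13 to -0.59 and those of the other 3 clones within -0.15 to 0.18. An exchange of arrays between clones was examined at 722 genes that set single clones apart. Of the 3 arrays 0 correlated best with another clone (0.931 to 0.963 with the own clone, 0.701 to 0.861 with the best other). These genes were chosen with the 3 arrays under their given labels, which favours the own clone. An exchanged array would nevertheless lie far from the other arrays at genes leading in its clone. The arrays agreed at Cd93 in clone 13-7 (9.44 ± 0.22, next clone 5.54) and Prxl2a in clone 16-18 (11.22 ± 0.27, next 7.83). They also agreed at Olfr60 in clone 13-11 (8.295 ± 0.18, next 4.48). Of the leading genes of these clones Hoxd1 in clone 13-11 varied most (9.50 ± 1.29, next 7.17). These values argue against an exchange of the 3 arrays. More carried-over macrophages or dendritic cells are argued against, since the 7 myeloid genes were lower in these arrays (median -1.123 over the 3). These genes do not measure B cells, on which clones 13-7 and 13-11 were kept. Carried-over B cells were not tested in these arrays. A difference in how these cultures were handled, or an interferon response in them, stays open. The labels give no group within a clone, so no biological explanation was tested.

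The myeloid transcripts of clones 13-11, 12-17 and 12-7 may come from macrophages or dendritic cells carried over from antigen-presenting cells. The 7 myeloid genes that passed as higher in clone 12-17 or lower in clone 3-10 were Lyz2, Spi1, Cybb, Mpeg1, C1qb, Itgax and Cd14. Ms4a6c, which passed in the opposite direction in both comparisons, was left out. The 7 genes deviated together from array to array. Their mean pairwise correlation was 0.619 against a median of 0.00664 in 10000 random lists of like expression, above 100% of them. The random lists were matched on mean expression and not on the spread between arrays, and the 7 genes were chosen from these data. Genes regulated together within the clones would also deviate together. The correlation thus does not tell carried-over cells from expression by the clones. Over all 22 markers it was 0.205, and without the 6 arrays that stand apart the 7 genes gave 0.497. More carried-over B cells in clone 13-11 than in clone 3-10 are argued against, since the median difference of 5 B cell genes between these clones was 0.0025 (highest 0.88, Cd22). Equal carry-over of B cells in both clones would give the same difference, so it was not tested. The source stays open, since clones 13-11 and 12-7 were kept on B cells while clone 3-10, kept on splenocytes, was lowest of the 6 in Lyz2 (7.62), Spi1 (6.89), Cybb (6.62), Mpeg1 (5.19), C1qb and Itgax, and myeloid-type expression by the clones themselves was not tested.

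Cd8a in clone 16-18 was 5.12 above the 4 clones lacking it (SE 0.18), and 2.95 in clone 12-7. CD8 T cells mixed into clone 16-18 are argued against, because Cd8b1 was -0.1231 from those 4 clones (95% interval -0.35 to 0.10), and in clone 12-7 it was -0.37. Dendritic cells bearing CD8a are argued against by a median difference of -0.06563 over 6 dendritic cell genes. Expression of CD8a by the CD4 clones is a hypothesis that was not tested.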

How the results depend on the processing

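The alternative without the 6 arrays that stand apart was chosen after seeing the data. Arrays were not paired by replicate number, since 25 of 60 same-numbered pairs had deviations correlating above 0.1. Their median was 0.0764, against -0.0229 for pairs of different numbers, and 16 of 24 arrays matched an array of their own number best. Some structure by replicate number is thus present, which the main fit leaves out. With the replicate block the counts were 6611 genes among clones, 25 and 5 between phenotypes, 262 and 222 for clone 12-17, and 198 and 334 for clone 3-10. Quantile normalization, median centring, a trended and robust fit, the filter, the mean of probe sets, every probe set tested and an adjusted p under 0.01 kept these counts within 1.5 times. Leaving out each array gave 5762 to 6255 genes among clones, 20 to 29 higher and 4 to 9 lower between phenotypes, 238 to 269 and 209 to 226 for clone 12-17, and 188 to 199 and 312 to 341 for clone 3-10. With no fold minimum the counts were 59 and 25, 646 and 504, and 711 and 753, and at 1.5-fold 52 and 14, 455 and 378, and 422 and 568, because fewer conditions were asked. Between phenotypes 39 genes were lower with clone 3-10 left out, 5 higher and 1 lower with clone 12-17 among the IL-13 clones, 3 lower with it among the IFN-g clones, and 12 lower without the 6 arrays; the cause was not tested beyond the change of clones and arrays. At clone level 0 genes passed in all settings that kept the clone as replicate, including leaving out each clone (0 to 0) and adjusted p under 0.2. Arrays as replicates gave 1495 and 1316, and with the replicate block 1599 and 1444, since these count arrays of 1 clone as samples of a phenotype. With clone as a random block 111 and 68 passed. This fit applied 1 consensus correlation of 0.229 between arrays of a clone to all genes, although 31.9% of genes differed among clones. Its counts therefore do not treat the clone as the replicate for those genes. Lists called went from 7, 11 and 15 to 0, 1 and 2 with an estimated correlation, and for phenotypes to 14 with arrays as replicates and 7 to 12 leaving out each clone (12 without clone 13-7); for clone 12-17 they fell to 7 without the 6 arrays. Leaving out each clone, the mean difference of the Th1 list ran from -0.26 (without clone 13-7) to 0.050 and that of the Th17 list from -0.66 to 0.044, both reversed without clone 16-18, and the interferon-stimulated list reversed to -0.11 without the 6 arrays, the 3 interferon-high arrays being among those left out. No background signal was given per probe set, so which of the lowest values lie above background is not known.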

Other observations

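The tests in this part were written down before their results were seen, except the comparison of clone choices. Il17re, of the Th17 list, ran from 5.91 ± 0.45 in clone 16-18 to 10.54 ± 0.10 in clone 12-17, with 10.48 ± 0.46 in clone 12-7. Clones 12-17 and 12-7, the pair with 490 genes apart, shared high Ambn (12.79 ± 0.11 and 12.95 ± 0.13), Maf (11.53 ± 0.09 and 11.39 ± 0.23) and Gja1 (9.60 ± 0.28 and 8.21 ± 0.30), with low Cd226 (5.34 ± 0.40 and 7.17 ± 0.49) against 11.30 to 12.39 in the other 4 clones. Ly6c2 ran from 5.83 ± 0.22 in clone 12-7 to 14.05 ± 0.03 in clone 3-10, and Pparg from 5.64 ± 0.18 in clone 3-10 to 11.74 ± 0.16 in clone 16-18.

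Genes that set a single clone apart from the other 5 lay beside each other more often than chance placing gives. Among them were 36 neighbouring pairs, against a median of 8 in 10000 random lists of the same sizes drawn from the 6221 genes that differed among clones, and the share of lists with as many was 1e-04, the smallest that number of lists can give. Of the 36 pairs 24 shared the first 3 letters of their symbols, such as C1qb with C1qc in clone 13-11. As many pairs as the remaining 12 were found in a share of 0.0679 of these lists and of 0.0086 of lists drawn from all genes. The 12 pairs do not bear on the 24, so whether the latter share probes was not tested.

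Regrouping single arrays breaks up clones that differ anyway, so low counts in most regroupings were fixed in advance. They show only that arrays of a clone are more alike than arrays of different clones. No explanation is excluded by them, and they say nothing about the clone as the unit. Of 100 regroupings of the 24 arrays, the real one included, 1 gave as many genes as the 6221 found among clones, the highest other being 56. For clone 12-17 against the IL-13 clones 1 of 100 regroupings of 12 arrays gave as many as the real 480, the highest other being 3. For clone 3-10 it was 3 of 100, with 529 in the real grouping and 600 and 597 in the highest others. In 3 of the other 99 regroupings all 4 arrays of 1 clone stayed together in the first group, and these gave 600, 597 and 423, which points to the clones as the structure of the samples. With the clone as the unit, setting apart clone 12-7 or 13-11 in place of 3-10 gave 472 and 423 genes, and setting apart clone 13-7 or 16-18 in place of 12-17 gave 161 and 235. For the 30 genes that separated the phenotypes, the 10 choices of 2 of 5 clones are too few for a share under 0.05; 6 of the 10 gave as many, and the highest other was 116.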
